A study of Mus musculus with 8 samples.

How the data were processed

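RNA from mouse epididymal fat pad was measured on Agilent 2-colour whole mouse genome arrays. The fat pad is the source name in the labels, and their protocols speak of epididymal fat and adipose tissue, but the sample titles, the tissue field and the design text say only epididymal tissue. Which part was taken was not settled here. Mice of the CFT Swiss albino strain, 5 weeks old, received saline, obestatin, its N-terminal peptide or the fragment analog Nt8U by intraperitoneal injection for 8 days. The labels' design text gives the dose as 80 ng/kg and 6 mice per group. The growth protocol in the labels gives 80 nmol/kg and 3 mice per group. These statements conflict and were not reconciled here. The series holds 8 samples, 2 per group, on 4 arrays. Replicate 1 of every group was labelled with Cy3 and replicate 2 with Cy5. No label says whether the samples of a group came from separate mice or pools, so p-values measure only the spread between these samples, which can be partly technical.

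The scanner values are spot intensities made by Feature Extraction 10.5.1.1 on a G2505C scanner, per the file headers. The deposited intensities used here are the median signal and the median background of each channel. The plan named mean signals, which were not used here. The deposited readme ties each channel to a sample and shows that both samples of a group shared an array. The authors also deposited a table of log2 values. Each column of that table followed the log2 median signal of 1 scanner channel (r = 1.00), but the columns labelled Cy3 matched the red channel and those labelled Cy5 the green. Channels were assigned by the readme here, and the group of every value is the same under either assignment. Under the labels of that table both samples of each group would trade replicate number and dye, so a value of 1 sample, or without it, would belong to the other sample of that group. The medians of the deposited log2 columns lay between -2.90 and -2.14, and every 75th percentile was 0. The authors used GeneSpring GX 10, scaled each peptide sample to the saline sample of the same dye and removed genes that differed 2-fold between the saline samples, per the deposited readme. Their deposited gene lists hold log2 fold changes and p-values of the authors' own test. The lists for the N-terminal peptide were used here, and of the lists for the other peptides only the stated sizes.

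Background was corrected with normexp (offset 50), arrays were normalized by loess within arrays and Aquantile between arrays, and each channel was then treated as a sample, with limma 3.58.1 in R 4.3.3. Because each array held 1 group, Aquantile gave the group means of all groups the same distribution over probes. Median signals of the samples lay between 73 and 231.5 intensity units, against median backgrounds of 22 to 31, and the number of arrays limits the precision. Control spots had weight 0 in loess and were then left out, and 78 probes were left out for an outlier mark. Saturated spots were kept. A spot counted as saturated when the files mark it or its signal was the highest the scanner gave (65527), because no Cy3 spot was marked although 10 to 37 of them per sample had that signal, beside 124 to 330 Cy5 spots. Spots of a probe were averaged. Of 41174 probes, 28164 were kept because they were well above background in both samples of at least 1 group and had no missing value, and 21596 were well above background in all samples. Gene names came from the platform annotation, updated through Entrez numbers with a mouse gene table of assembly GRCm38.p6. It lists 32664 probes with 1 symbol and 45 with several, and does not list 8465, which stay unnamed here. No coordinates are given, because the genome build of the array design was not matched to that assembly. The brightest probe stood for each of the 15443 genes.

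A linear model with group means and a dye term was fitted to all 8 samples (3 residual degrees of freedom, 1.67 prior degrees of freedom), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment, with a threshold of 0.05 and two-sided tests. The planned random block for the array could not be fitted, because each array held the samples of 1 group. Array and group cannot be told apart, and no p-value here includes the variation between arrays. A list of genes was tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Of 31 lists, 30 had at least 5 measured genes and were tested, and an erythroid list was not. Of the 731 symbols in the lists, 729 matched a current gene, 10 of them under a newer name. A probe not well above background in a whole group has only a bound there. For such a bound the mean of the brighter group was set against the lowest signal well above background in each dim sample, or the probe's own signal where higher. A probe saturated in a whole group likewise has only a bound there, from the means of both groups. Each group held both dyes equally in these bounds, except in those without 1 or 3 samples.

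The lists, the comparisons, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes genes past the threshold whose peptide samples both lie on the same side of both saline samples. Where none passed in a direction, it takes the 5 with the smallest p in that direction, given as values and not as changes. It adds up to 4 members of each described list with the largest absolute log2 fold change, a fixed set of ghrelin and adipose genes, and the 5 largest entries in each direction of the authors' lists.

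The procedure was tested on simulated data for obestatin against saline with 15443 genes and the fitted spread of each gene. Of 50 genes changed by 1, 2, 3 or 4 on the log2 scale, 0 passed the adjusted threshold at each size, and 27, 40, 42 and 48 had an unadjusted p under 0.05. Of the unchanged genes, 5.29% had an unadjusted p under 0.05. With a spread of 0.2 for every gene, 46, 50, 50 and 50 passed, with 5 unchanged genes called. A count of 0 genes at the spread of these samples therefore excludes none of these sizes. A simulated list shifted by 1 gave a median of 1.04, with an adjusted p of 4.06e-16 in camera at the preset correlation and 0.11 with an estimated correlation, and 0 of 29 unchanged lists were called. Simulated noise was independent between genes, but list members often moved together between real samples of a group. How often unchanged genes have p under 0.05, or camera at the preset correlation calls unchanged lists, is thus unknown in these data. The alternatives covered the background correction, the authors' values, the normalization within and between arrays, the filter on dim probes, the dye term, the variance prior, the handling of several probes, the set test, the threshold and leaving out each sample. The other 2 alternatives were chosen after seeing the data: scores of the germ cell and epididymis lists as covariates in place of the dye term, and a fit without the 3 samples highest in germ cell genes. The former cannot test those lists, whose scores it includes. The latter has no dye term and leaves 1 sample of saline, the N-terminal peptide and Nt8U, each assumed to vary like the obestatin pair, which alone gives its spread.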

Results

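Expression in the epididymal fat pad was compared across 4 groups of 2 samples, from mice given saline, obestatin, the N-terminal peptide of obestatin or its analog Nt8U. The labels name fat in some fields and epididymal tissue in others. Obestatin is a peptide made from the same precursor as ghrelin, a hormone of the stomach. Each sample was 1 channel of a 2-colour array, and both samples of a group shared an array. Of 41174 probes, 25360 and 28574 were well above background in saline replicates 1 and 2, 26920 and 29341 in obestatin, 25821 and 29093 in the N-terminal peptide, and 25035 and 30697 in Nt8U. The median signal of a sample lay between 73 and 231.5 intensity units, against a median background of 22 to 31. The number of arrays limits the precision: the median SE of a log2 difference between groups was 0.47, so that a gene of median spread needed a difference of 1.24 for an unadjusted p of 0.05. The samples of a group differed by over 2-fold in 51.4% of the 15443 genes for saline, 8.78% for obestatin, 57.0% for the N-terminal peptide and 36.4% for Nt8U.

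Germ cell and epididymis genes differed widely between the samples of a group. The median of 20 testis germ cell genes was 9.19 and 15.08 on the normalized log2 scale in saline replicates 1 and 2, 9.59 and 14.96 in the N-terminal peptide, and 8.77 and 13.84 in Nt8U. All 20 genes were over 4-fold higher in replicate 2 in each of these groups, while in obestatin the medians were 11.28 and 9.91. In these Cy5 samples 7, 9 and 7 of the 20 genes were saturated, so the differences of those genes are understated. Prm2, which packs DNA in sperm, was saturated there and stood at 16.53 and 15.33 in the obestatin samples, which were not saturated. Prm2 and Lcn5 were singled out after their values were seen. Of 19 epididymis genes, the median was 16.16 and 10.12 in saline, 8.90 and 8.57 in obestatin, 11.65 and 7.01 in the N-terminal peptide, and 6.37 and 6.62 in Nt8U. Lcn5, a lipocalin secreted by the epididymis, stood at 16.48 and 12.73 in saline, 15.09 and 15.16 in obestatin, and 16.92 and 12.87 in the N-terminal peptide, and it was saturated in replicate 1 of saline and the N-terminal peptide and in obestatin replicate 2. It was not well above background in Nt8U replicate 1 and stood at 8.98 in replicate 2. The correlation across genes was 0.648 between the saline samples and 0.984 between replicate 2 of saline and replicate 2 of the N-terminal peptide, though genes are not independent replicates.

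**Figure D1:**
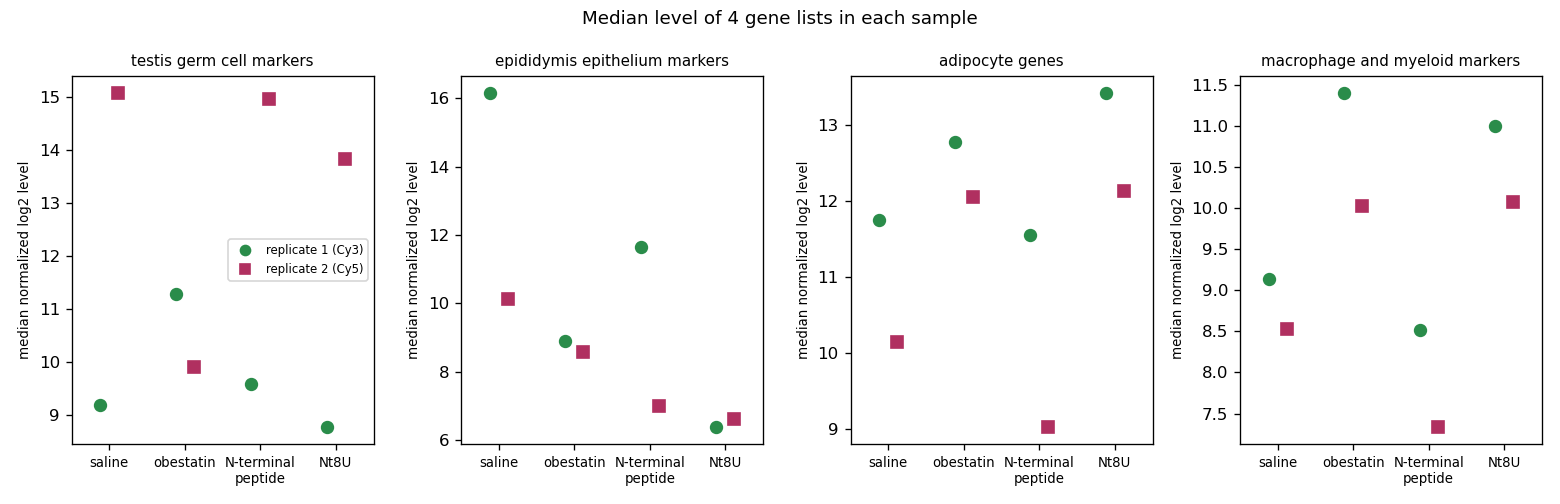
Median normalized log2 level of 4 gene lists (testis germ cell, epididymis, adipocyte, macrophage) in each of the 8 samples, with green circles for replicate 1 (Cy3) and red squares for replicate 2 (Cy5). The germ cell medians of replicate 2 lay at 15.08 in saline, 14.96 in the N-terminal peptide and 13.84 in Nt8U, against 8.77 to 9.59 in replicate 1 of these groups.

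Obestatin was first compared with saline. Macrophage genes were higher with obestatin, with a median log2 fold change of 1.65 over 26 genes, 25 of them higher in both dyes. Among them Cd163, a scavenger receptor of tissue macrophages, differed by 2.94 (SE 0.56, n = 2 per group), Ccl6, a chemokine, by 3.04 (SE 0.77), and Csf1r, the receptor for macrophage colony-stimulating factor, by 1.95 (SE 0.23). Endothelial genes (median 1.89 over 18 genes) and adipocyte genes (median 1.65 over 25 genes) were higher as well. Pparg and Cebpa, transcription factors of adipocyte differentiation, differed by 2.40 (SE 0.51) and 2.26 (SE 0.72), and Pecam1 and Emcn, endothelial surface proteins, by 2.14 (SE 0.30) and 2.11 (SE 0.53). Epididymis genes were lower, with a median of -2.97 over 19 genes and 10 of them lower in both dyes.

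Of 30 lists, camera at the preset correlation found 18 shifted with obestatin, 15 higher and 3 lower. The adjusted p of the macrophage list was 1.74e-15, of the endothelial list 1.59e-11, of the adipocyte list 1.4e-07 and of the epididymis list 0.000329, and for each of them the adjusted p = 0.499 with an estimated correlation. With fry, 2 lists were shifted, macrophage and B cell genes (adjusted p = 0.0334 for each). Adjusted over the list alone, 17 macrophage, 13 endothelial, 10 matrix, 7 interferon, 4 fibroblast, 4 B cell and 5 epididymis genes passed, and 0 of the adipocyte genes. The matrix list, with collagens, was higher by a median of 1.45 (adjusted p = 4.09e-11), with Fn1, which encodes fibronectin, at 2.81 (SE 0.36) and Lox, a collagen cross-linking enzyme, at 2.24 (SE 0.76). The fibroblast list was higher by 1.60 (adjusted p = 8.33e-07), with Sfrp2, a secreted modulator of Wnt signalling, at 3.63 (SE 0.85). Interferon response genes were higher by 1.22 (adjusted p = 3.22e-10), with Gbp2 at 2.10 (SE 0.32) and Cxcl9 at 1.98 (SE 0.55), both induced by interferon. B cell genes were higher by 0.73 (adjusted p = 0.00502). For these 4 lists too the adjusted p = 0.499 with an estimated correlation. Without obestatin replicate 1 the B cell (0.77) and epididymis medians (-3.91) did not pass, the interferon median was 0.77 without obestatin replicate 2, and the epididymis median was -1.93 and -4.46 without saline replicates 1 and 2. B cell (0.49) and fibroblast genes (0.73) did not pass without the 3 samples highest in germ cell genes, nor did B cell genes (0.82) with germ cell and epididymis scores as covariates. Adipocyte, matrix, interferon and epididymis medians were 1.08, 0.62, 0.70 and -5.30 without those 3 samples, and the B cell median was 1.49 with the scanner software's processed signals and 0.18 with no filter on dim probes.

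Lipid genes were higher with obestatin by smaller medians. The median was 1.03 for lipolysis and lipid droplet genes (adjusted p = 0.00502), 0.61 for fatty acid and triglyceride synthesis (0.00767), 0.45 for fatty acid oxidation (0.00897), 1.14 for lipoprotein transport (0.000684) and 0.62 for insulin signalling (0.00221). Ces1d, a triglyceride lipase, differed by 2.80 (SE 1.06), and Plin1, a lipid droplet coat protein, by 1.98 (SE 0.77). Thrsp, a lipogenic gene, differed by 2.06 (SE 0.68), and Acacb, which makes malonyl-CoA, by 1.94 (SE 0.67). Immediate early genes were higher by 0.68 (adjusted p = 0.00146), with 1 gene passing when adjusted over the list alone, and mesothelial genes by 0.78 (0.031). For these 7 lists the adjusted p = 0.499 with an estimated correlation. Smooth muscle genes were higher by 1.23 (adjusted p = 0.0171), cell cycle genes lower by a median of -1.06 (0.0016) and ribosomal protein genes by a median of -0.35 (0.000592). With an estimated correlation their adjusted p = 0.548, 0.548 and 0.591. Of 51 ribosomal genes 25 were saturated in obestatin replicate 2, beside 9 and 6 in saline replicates 1 and 2, 4 and 20 in the N-terminal peptide and 0 and 23 in Nt8U, so differences of this list are limited by saturation in every comparison. The cell cycle median was 0.52 in the Cy3 and -2.58 in the Cy5 samples, and germ cell genes lay at 2.61 and -4.66 (camera adjusted p = 0.202). Oxidative phosphorylation (-0.17, adjusted p = 0.208), tricarboxylic acid cycle (0.24, 0.202), heat shock (-0.34, 0.661) and cholesterol genes (0.868) did not pass. For cholesterol genes the median was 0.17 while the mean was -0.036 and camera gave a lower direction. Leaving out obestatin replicate 1, lipolysis (1.33), smooth muscle (1.41) and ribosomal genes (-0.26) did not pass, while the other medians of these lists were 1.11 for synthesis, 0.85 for fatty acid oxidation, 1.95 for lipoprotein, 1.22 for insulin, 1.26 for immediate early, 1.85 for mesothelial and -2.49 for cell cycle genes. Leaving out obestatin replicate 2, synthesis (0.55), fatty acid oxidation (0.36), lipoprotein (0.29), insulin (0.17), immediate early (0.37), mesothelial (0.45), smooth muscle (1.07) and cell cycle genes (0.31) did not pass. Leaving out saline replicate 1, synthesis (0.55), lipolysis (0.16) and ribosomal genes (-0.14) did not pass, and fatty acid oxidation, immediate early, mesothelial and cell cycle medians were 0.70, 1.075, 1.405 and -1.63. Leaving out saline replicate 2, immediate early (0.55), mesothelial (0.14), smooth muscle (0.13) and cell cycle genes (-0.52) did not pass, and synthesis, lipolysis, lipoprotein and ribosomal medians were 1.07, 1.67, 0.48 and -0.63. With germ cell and epididymis scores as covariates, synthesis (0.23), fatty acid oxidation (0.35), insulin (0.56) and lipolysis genes (0.63) did not pass, immediate early, mesothelial and smooth muscle medians were 1.20, 1.61 and 2.74, and the ribosomal median turned to 0.175, as it did with quantile normalization (0.13). Ribosomal genes did not pass without loess (-0.041) or in the authors' log2 values (0) either, nor did mesothelial genes with the scanner software's processed signals (0.95). Without the 3 samples highest in germ cell genes, synthesis (0.51), fatty acid oxidation (0.295), lipoprotein (0.013), insulin (0.33), immediate early (0.265), mesothelial (0.36) and smooth muscle genes (0.16) did not pass, the cell cycle median turned to 0.40 and did not pass, and the ribosomal median was -0.72. The fatty acid oxidation median was 0.74 with quantile normalization, 0.815 without loess and 0.89 in the authors' log2 values, and the insulin median 0.40 with the mean of all probes.

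No single gene passed the adjusted threshold for obestatin against saline: limma gave 0 genes, with 1566 at an unadjusted p under 0.05 (1251 higher, 315 lower) and a lowest adjusted p of 0.529. The smallest p among higher genes belonged to C1qc, a complement subunit (2.17, SE 0.25), Csf1r, Stab1, a macrophage scavenger receptor (2.03, SE 0.24), H2-Ab1, a class II antigen presentation gene (2.18, SE 0.26), and the taste receptor gene Tas2r105 (at least 3.36-fold). Those among lower genes were Cstdc2 (-7.88, SE 1.30), Syt6 (-2.38, SE 0.44), Vgll1 (at least 2.22-fold), Erv3 (-1.63, SE 0.32) and Apol8 (-1.37, SE 0.27), all with a limma adjusted p of 0.529. Lep, the leptin gene, differed by 2.14 (SE 0.61, adjusted p = 0.543), Retn, resistin, by 2.15 (SE 0.87) and Adipoq, adiponectin, by 1.77 (SE 0.81). Adipoq and Lpl (1.095, SE 1.54) were saturated in 1 of the 2 obestatin samples. Fasn was saturated in both, and the lower limit of its fold was 1.25 (adjusted p = 0.771), but 0.787 without obestatin replicate 1 and 2 without obestatin replicate 2, so no direction is given for it. Lipe stood at 1.03 (SE 0.88), Ghrl, the ghrelin and obestatin precursor, at -1.56 (SE 1.15) and Gpr39, a receptor proposed for obestatin, at -0.78 (SE 0.47). Glp1r was well above background in 0 samples and was not tested. Epididymis genes went both ways: Lcn8 was at -6.70 (SE 1.46) and Rnase10 at -6.69 (SE 1.40), while Spint4 was at least 217-fold higher (adjusted p = 0.546), or at least 581- and 80.8-fold without obestatin replicates 1 and 2. Cstdc2, Lcn8, Lcn9 and Cst11 were saturated in saline replicate 1, so their differences from saline are understated. The samples of both groups did not overlap in 39.1% of genes, against 33.3% by chance for exchangeable samples. Samples of different groups with the same replicate number were often closer than those of a group, so that 33.3% is not the share to expect without a change, here or in the other comparisons. Genes were called by limma without obestatin replicate 1, most of them lower, but that fit leaves 1 obestatin sample, assumed to vary like the other groups. Its dye term rests on groups whose Cy5 samples were all high in germ cell genes. Those calls are therefore not taken as changes.

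The N-terminal peptide was compared likewise, and the fat pad lists lay lower. Macrophage genes had a median of -0.70 over 26 genes, 22 of them lower in both dyes (camera adjusted p = 3.02e-18, and adjusted p = 0.425 with an estimated correlation). Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, differed by -1.38 (SE 0.26, n = 2 per group), and Ccl6 by -1.67 (SE 0.77). Adipocyte genes had a median of -1.02 (adjusted p = 9.02e-14, and adjusted p = 0.658 with an estimated correlation), which was 0.13 in the Cy3 and -2.30 in the Cy5 samples. Their members with the largest differences were Lpl, lipoprotein lipase (-2.72, SE 1.54), Sncg (-1.91, SE 0.74), Retn (-1.91, SE 0.87) and Lep (-1.77, SE 0.61). Epididymis genes were lower too, by a median of -1.70 with 13 of 19 lower in both dyes (adjusted p = 1.25e-10, and adjusted p = 0.658 with an estimated correlation), while germ cell genes lay at 0.013 (0.82). Without N-terminal peptide replicate 2 the adipocyte median was -0.052 and did not pass, and it was -2.06 without replicate 1 of that group and -0.62 without saline replicate 2, where the macrophage median was -0.46. The epididymis median was -3.34 and -0.049 without N-terminal peptide replicates 1 and 2, and 0.20 and -3.72 without saline replicates 1 and 2, with a lower direction in camera each time. The adipocyte median turned to 0.125 without the 3 samples highest in germ cell genes and did not pass.

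Camera found 10 of 30 lists shifted with the N-terminal peptide, all lower, against 0 with an estimated correlation and 0 with fry. Matrix genes had a median of -0.64 (adjusted p = 4.24e-12), with Col5a2, a collagen chain, at -1.36 (SE 0.49), and fibroblast genes -0.67 (5.27e-11), with Lum and Dpt, matrix proteins, at -2.27 (SE 0.96) and -1.51 (SE 0.40). B cell genes had a median of -0.23 (adjusted p = 0.0292), with Ighm, an immunoglobulin heavy chain, at -1.26 (SE 0.29). For these 3 lists the adjusted p = 0.608 with an estimated correlation. Lipoprotein transport (-0.54, adjusted p = 1.66e-05), endothelial (-0.30, 0.000949), interferon (-0.27, 0.00116) and fatty acid oxidation genes (-0.23, 0.02) each had an adjusted p = 0.715 with an estimated correlation. Adjusted over the list alone, 5 genes passed, all in the epididymis list. The lists for fatty acid synthesis (-0.15, adjusted p = 0.167), lipolysis (-0.10, 0.0822), oxidative phosphorylation (0.078, 0.0708), cell cycle (0.17, 0.0714), mesothelium (-0.26, 0.115), immediate early (-0.13, 0.735) and heat shock genes (0.027, 0.818) did not pass. Nor did insulin signalling (median 0.025, mean -0.012, camera higher, adjusted p = 0.818), tricarboxylic acid cycle (0.007, -0.032, higher, 0.818), ribosomal (0.003, -0.002, higher, 0.82) and smooth muscle genes (0.002, -0.104, lower, 0.735). Leaving out N-terminal peptide replicate 2, matrix (-0.071), fibroblast (-0.13), lipoprotein (-0.13), endothelial (-0.083), interferon (-0.075) and fatty acid oxidation genes (-0.11) did not pass. Leaving out N-terminal peptide replicate 1, the fatty acid oxidation median (-0.25) did not pass, and matrix, fibroblast, lipoprotein, endothelial and interferon medians were -1.21, -1.33, -0.97, -0.65 and -0.51. Fatty acid oxidation genes did not pass without saline replicate 1 (-0.28) or 2 (-0.225), lipoprotein genes without saline replicate 1 (-0.26), and interferon (-0.34) and endothelial genes (-0.086) without saline replicate 2. The endothelial median was -0.595 without saline replicate 1, and lipoprotein and fibroblast medians were -0.82 and -1.12 without saline replicate 2. B cell genes did not pass without any 1 of the saline (-0.25, -0.15), obestatin (-0.23 for both) or N-terminal peptide samples (-0.18, -0.23). With germ cell and epididymis scores as covariates, matrix (-0.29), fibroblast (-0.355), lipoprotein (-0.24) and B cell genes (-0.34) did not pass, and fatty acid oxidation and endothelial medians were -0.44 and -0.60. In the fit without the 3 samples highest in germ cell genes, interferon (-0.10), lipoprotein (-0.22), fatty acid oxidation (-0.093) and B cell genes (-0.19) did not pass, the endothelial median turned to 0.18 and did not pass, and the matrix median was -0.42. Fatty acid oxidation and B cell genes (-0.23 each) did not pass without the dye term, nor did B cell genes with no filter on dim probes (-0.027). The scanner software's processed signals gave B cell, endothelial and fibroblast medians of -0.58, -0.46 and -1.011.

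For the N-terminal peptide limma called 0 genes, with 166 at an unadjusted p under 0.05 (29 higher, 137 lower) and a lowest adjusted p of 1. The smallest p among lower genes belonged to Cstdc2 (-7.68, SE 1.30), Lyve1, the epididymis genes Lcn9 (-7.39, SE 1.41) and Lcn8 (-7.49, SE 1.46), and Six3 (at least 2.3-fold). Those among higher genes, Rtp1, Ctsq, Olfr514, Olfr472 and Olfr1370, were at least 2.99-, 2.7-, 2.13-, 1.75- and 1.7-fold higher, each with a limma adjusted p of 1. Spint4 was at least 154-fold higher and Cst11 was at -7.47 (SE 1.52), also with an adjusted p of 1. The bound for Spint4 was 14.9-fold without N-terminal peptide replicate 1, 1600-fold without its replicate 2 and 1520-fold without the 3 samples highest in germ cell genes. Adipoq stood at -1.36 (SE 0.81), Pparg at -0.65 (SE 0.51), Fasn at -0.50 (SE 0.56), Lipe at -0.13 (SE 0.88), Ghrl at 0.27 (SE 1.15) and Gpr39 at 0.077 (SE 0.47). The samples did not overlap in 9.1% of genes, against 33.3% by chance for exchangeable samples, which these are not: r across genes was 0.958 and 0.984 between replicates 1 and between replicates 2 of both groups, beside 0.648 and 0.621 within the groups. The number of shifted lists was 5 without N-terminal peptide replicate 2, 18 without N-terminal peptide replicate 1 and 4 without the 3 samples highest in germ cell genes.

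Nt8U was then compared with saline. Fat pad lists lay higher: endothelial genes by a median of 1.89 over 18 genes, adipocyte genes by 2.02 over 25, 23 of them higher in both dyes, and macrophage genes by 1.36 over 26, 25 of them higher in both dyes. Thrsp differed by 3.47 (SE 0.68, n = 2 per group), Pparg by 2.90 (SE 0.51), Lep by 2.72 (SE 0.61), Sncg by 3.00 (SE 0.74) and Plin1 by 2.71 (SE 0.77). Cd163 differed by 2.94 (SE 0.56), Ccl6 by 2.99 (SE 0.77) and Robo4, an endothelial receptor, by 2.32 (SE 0.40). Epididymis genes were lower by a median of -5.27, with 17 of 19 lower in both dyes, and the germ cell median was -0.71 (camera adjusted p = 0.159). Of the 19 epididymis genes, 7 were saturated in saline replicate 1. Some, such as Lcn5 and Cst11, were not well above background in Nt8U replicate 1, so the size of their list's median may be understated.

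Camera found 21 of 30 lists shifted with Nt8U, 17 higher and 4 lower. The adjusted p was 1.8e-15 for endothelial, 6.34e-16 for macrophage and 9.07e-13 for epididymis genes, and with an estimated correlation the adjusted p = 0.29 for each. For adipocyte genes it was 2.13e-12, and the adjusted p = 0.302 with an estimated correlation. With fry, macrophage and B cell genes were shifted (adjusted p = 0.0419 for each). Adjusted over the list alone, 14 endothelial, 10 macrophage, 10 matrix, 8 adipocyte, 4 interferon, 4 mesothelial, 3 fibroblast, 3 smooth muscle, 2 B cell, 1 immediate early and 6 epididymis genes passed. Matrix genes were higher by 1.38 (adjusted p = 4.98e-13), with Lama4, a laminin chain, at 2.50 (SE 0.60) and Fn1 at 2.46 (SE 0.36), and interferon genes by 0.87 (4.53e-11), with Gbp2 at 2.26 (SE 0.32) and Rsad2 at 2.07 (SE 0.36). Fibroblast genes were higher by 1.32 (adjusted p = 1.12e-06), with Fbln2 and Sfrp2 at 2.90 (SE 0.54) and 2.84 (SE 0.85), and B cell genes by 0.33 (0.038). For these 4 lists the adjusted p = 0.29 with an estimated correlation. The epididymis median was -3.14 without Nt8U replicate 1, -2.96 without saline replicate 1 and -8.28 without saline replicate 2, and the fibroblast median 0.80 without Nt8U replicate 2. B cell genes did not pass without Nt8U replicate 1 (0.16), saline replicate 2 (0.61) or either sample of the N-terminal peptide (0.33), and lay at 0.55 without Nt8U replicate 2 and 0.17 without saline replicate 1. Fibroblast (0.675) and B cell genes (0.72) did not pass without the 3 samples highest in germ cell genes, nor did B cell genes (0.29) with germ cell and epididymis scores as covariates, where endothelial and fibroblast medians were 1.26 and 2.56. B cell genes did not pass with quantile normalization (0.35), without loess (0.29), without the dye term (0.33) or with no filter on dim probes (0.045). The epididymis median was -9.40 without those 3 samples and -8.18 with the scanner software's processed signals, which gave 1.275 for B cell genes.

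The lipid lists were higher with Nt8U as well. Medians were 1.001 for fatty acid synthesis (adjusted p = 2.96e-06), 1.47 for lipolysis (4.14e-06), 0.86 for fatty acid oxidation (8.57e-07), 0.67 for the tricarboxylic acid cycle (1.15e-05) and 0.62 for insulin signalling (1.68e-05), each with an adjusted p = 0.29 with an estimated correlation. Acacb differed by 2.76 (SE 0.67). Lipoprotein transport genes were higher by 1.099 (adjusted p = 6.87e-05, and adjusted p = 0.345 with an estimated correlation), with Gpihbp1, the endothelial anchor of lipoprotein lipase, at 2.58 (SE 0.77). Oxidative phosphorylation (0.16, adjusted p = 0.0133) and mesothelial genes (1.07, 0.00209) were higher, with an adjusted p = 0.319 for each with an estimated correlation. Smooth muscle genes were higher by 1.39 (adjusted p = 9.79e-05, and adjusted p = 0.41 with an estimated correlation), with Synpo2, an actin-binding protein, at 3.42 (SE 0.63), but the list's median was -0.51 in the Cy3 and 3.20 in the Cy5 samples, and 5 of 16 genes were saturated in Nt8U replicate 2. Immediate early genes were higher by 0.60 (adjusted p = 0.00424, and adjusted p = 0.512 with an estimated correlation). Ribosomal (-0.57, adjusted p = 1.2e-08), cell cycle (-0.70, 0.00141) and heat shock genes (-0.59, 0.0426) were lower, with adjusted p = 0.487, 0.553 and 0.616 with an estimated correlation. Cell cycle genes were higher in replicate 2 than in replicate 1, by 2.625 in saline and 2.047 in Nt8U. Germ cell genes were too, by 5.258 and 4.558. With the germ cell and epididymis scores as covariates, ribosomal genes (median 0.42, adjusted p = 0.000598) and heat shock genes (0.71, adjusted p = 0.00628) passed in the other direction, and the fatty acid synthesis, lipolysis, fatty acid oxidation, tricarboxylic acid cycle and insulin lists no longer passed (medians 0.20, 0.26, 0.60, 0.26 and 0.64), nor did oxidative phosphorylation (-0.14), while immediate early, lipoprotein, mesothelial and smooth muscle medians were 1.65, 1.67, 2.99 and 4.425. A fit without the 3 samples highest in germ cell genes ended the calls of lipoprotein (0.41), immediate early (0.15), mesothelial (0.77) and cell cycle genes (-0.32), and the smooth muscle median turned to -0.51 and did not pass. Synthesis, lipolysis, tricarboxylic acid cycle, oxidative phosphorylation, ribosomal and heat shock medians were 1.615, 2.43, 1.03, 0.43, -1.18 and -1.24 in that fit. Ribosomal (-0.17) and heat shock genes (-0.40) did not pass with quantile normalization, nor did heat shock genes with the mean of all probes (-0.55) or with no filter on dim probes (-0.59). The oxidative phosphorylation median was 0.455 with quantile normalization, 0.36 without loess and 0.39 in the authors' log2 values. Leaving out Nt8U replicate 1, ribosomal (-0.086), heat shock (-0.17) and oxidative phosphorylation genes (0.089) did not pass, and lipolysis, immediate early, mesothelial and smooth muscle medians were 0.90, 1.04, 1.85 and 3.32. Leaving out Nt8U replicate 2, immediate early (0.21), mesothelial (0.445) and smooth muscle genes (-0.33) did not pass, and ribosomal, heat shock and oxidative phosphorylation medians were -1.12, -1.23 and 0.30. Leaving out saline replicate 1, heat shock (-0.25) and oxidative phosphorylation genes (0.038) did not pass, and lipolysis, cell cycle, immediate early, ribosomal and smooth muscle medians were 0.85, -1.40, 0.97, -0.34 and 2.38. Leaving out saline replicate 2, cell cycle (0.004), immediate early (0.27), mesothelial (0.87) and smooth muscle genes (0.50) did not pass, and lipolysis, lipoprotein, heat shock and oxidative phosphorylation medians were 2.28, 0.51, -1.02 and 0.375. Heat shock genes did not pass without either obestatin sample (-0.59).

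For Nt8U limma called 0 genes, with 1446 at an unadjusted p under 0.05 (1179 higher, 267 lower) and a lowest adjusted p of 0.451. The smallest p among higher genes belonged to Ighm (2.72, SE 0.29), Dusp1, a phosphatase of MAP kinases (1.91, SE 0.23), Acp5, an acid phosphatase of macrophages and osteoclasts (2.76, SE 0.34), Csf1r (1.84, SE 0.23) and C1qc (2.01, SE 0.25). Those among lower genes were Ap1s2 (-6.89, SE 1.15), Cstdc2 (-7.56, SE 1.30), Apol8 (-1.53, SE 0.27), Six3 (at least 2.41-fold) and Lcn8 (at least 198-fold), all with a limma adjusted p of 0.451. The bound for Lcn8 was 29.7-fold without saline replicate 1, 1320-fold without saline replicate 2 and 1380-fold without the 3 samples highest in germ cell genes. Rnase10 was at -7.35 (SE 1.40). Retn stood at 2.70 (SE 0.87), Lipe at 1.79 (SE 0.88), Ghrl at -0.72 (SE 1.15) and Gpr39 at -0.42 (SE 0.47). Adipoq, Lpl and Fasn were saturated in both Nt8U samples, which sets Adipoq at least 3.33-fold and Lpl at least 2.19-fold higher (adjusted p = 0.719 and 0.984). The lower limit for Fasn was 1.25-fold (adjusted p = 0.984), but 0.891 without Nt8U replicate 1, so no direction is given for it. The samples did not overlap in 25.6% of genes, against 33.3% by chance for exchangeable samples. Without the 3 samples highest in germ cell genes limma called 33 genes, all lower, but that fit sets 1 Nt8U sample against 1 saline sample and assumes for both the spread of the obestatin pair, the smallest of the 4 groups.

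The remaining 9 lists passed in no comparison with saline. For obestatin, the N-terminal peptide and Nt8U in this order, medians were 0.27, -0.016 and 0.070 for thermogenic genes, 0.17, -0.14 and -0.003 for cholesterol genes and 0.26, 0.098 and 0.40 for clock genes. For the list of ghrelin and feeding peptides they were 0.39, 0.066 and 0.32, for T cells 0.28, 0.081 and 0.15, for germ cells -1.14, 0.013 and -0.71 and for skeletal muscle 0.17, -0.027 and 0.18. For pancreas they were 0.26, 0.043 and -0.005, and for nerve 1.31, -0.35 and 0.040. The lowest adjusted p of camera among them was 0.0698, for clock genes with Nt8U. For T cell genes with the N-terminal peptide and with Nt8U, and for pancreas and cholesterol genes with Nt8U, the median and camera's direction differed in sign, as for skeletal muscle with the N-terminal peptide.

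**Figure D2:**
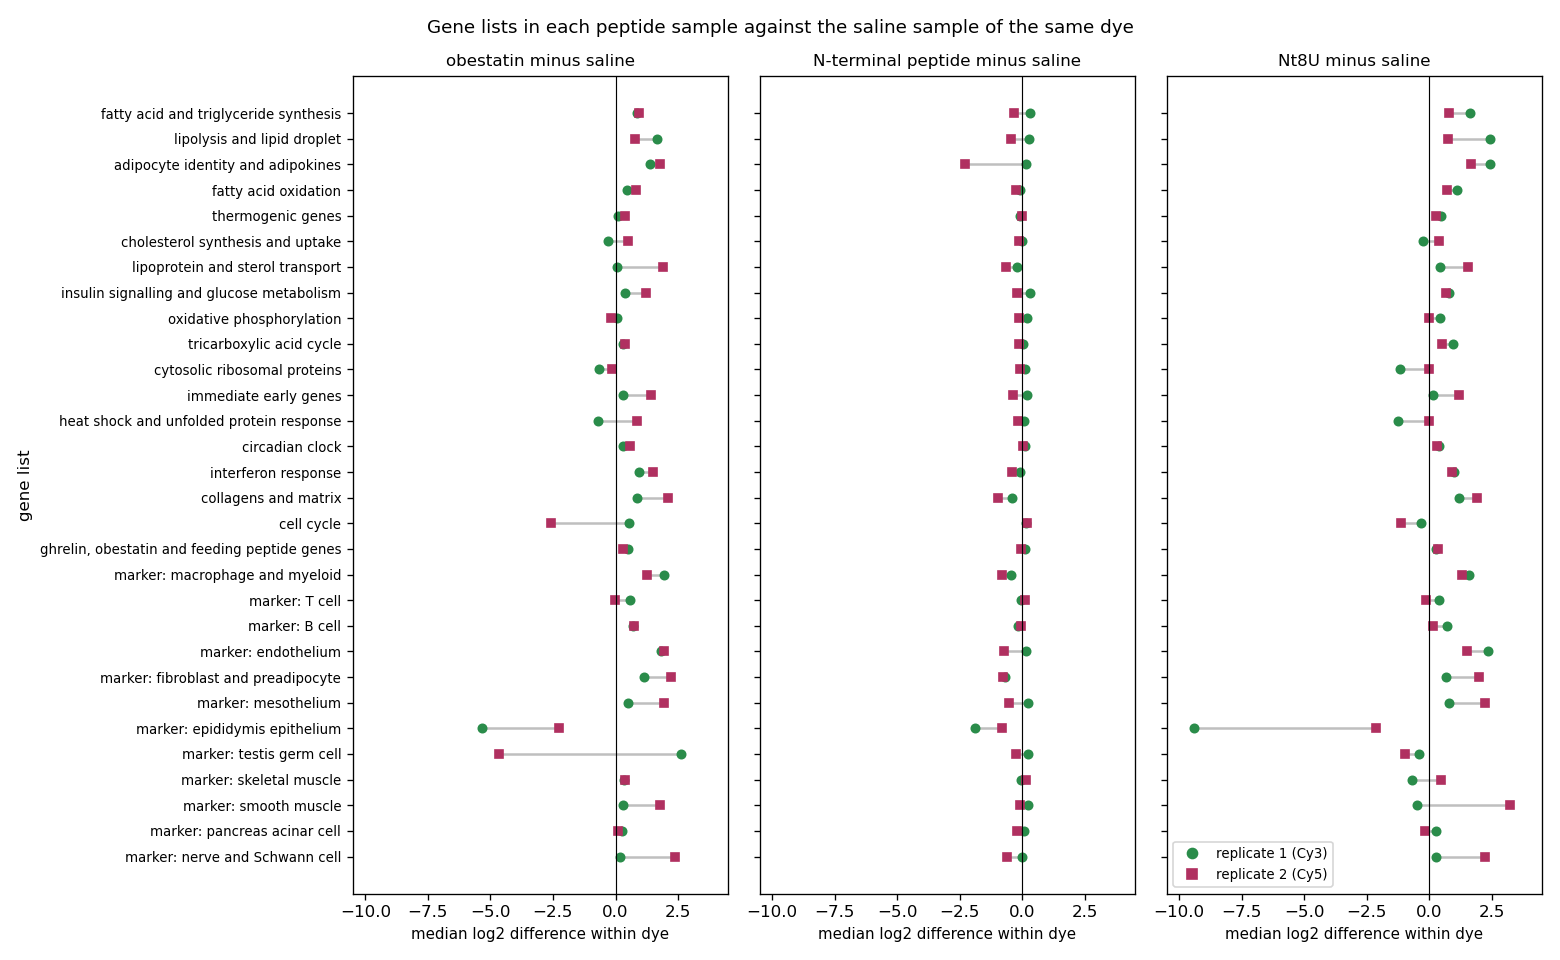
Median log2 difference from saline within each dye for 30 gene lists and 3 peptides, with green circles for the Cy3 samples, red squares for the Cy5 samples and a grey line joining them. Macrophage genes lay at 1.94 and 1.27 with obestatin, -0.47 and -0.82 with the N-terminal peptide and 1.57 and 1.29 with Nt8U.

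The peptides were then set against each other at the same stated dose and time. Macrophage genes were lower with the N-terminal peptide than with obestatin by a median of -2.39, with 25 of 26 lower in both dyes (camera adjusted p = 1.72e-19, and adjusted p = 0.388 with an estimated correlation). Adipocyte genes had a median of -2.83 (adjusted p = 1.49e-12, and adjusted p = 0.463 with an estimated correlation). Matrix (-2.37, adjusted p = 1.09e-14), endothelial (-2.05, 1.32e-12), fibroblast (-2.27, 2e-10) and interferon genes (-1.44, 5.25e-11) were lower too, each with an adjusted p = 0.458 with an estimated correlation. In all 17 of 30 lists were shifted, 15 lower and 2 higher, the latter cell cycle (1.32, adjusted p = 0.000174) and ribosomal genes (0.38, 0.00117), with adjusted p = 0.585 and 0.659 with an estimated correlation. Adjusted over the list alone, 107 genes passed, among them 23 macrophage, 18 matrix, 17 adipocyte, 14 endothelial, 12 fibroblast and 12 interferon genes. With fry, macrophage and B cell genes were shifted (adjusted p = 0.0133 for each). Epididymis (-0.23, adjusted p = 0.845) and germ cell genes (1.30, 0.248) did not pass, and for the former the median and camera's direction differed in sign. Of the lipid lists, lipoprotein transport (-1.36, adjusted p = 3.15e-06), lipolysis (-1.16, 0.00117), fatty acid oxidation (-0.80, 0.00117), synthesis (-0.71, 0.00213) and insulin signalling genes (-0.59, 0.00803) were lower, as were mesothelial genes (-1.01, 0.00701), each with an adjusted p = 0.463 with an estimated correlation. Also lower were B cell (-0.86, adjusted p = 0.00215), immediate early (-0.74, 0.00143) and smooth muscle genes (-1.145, 0.0152), with adjusted p = 0.458, 0.566 and 0.615 with an estimated correlation. With obestatin replicate 2 left out, cell cycle (-0.18), synthesis (-0.79), fatty acid oxidation (-0.54), insulin (-0.23), immediate early (-0.61), mesothelial (-0.61) and smooth muscle genes (-0.915) did not pass, and interferon and lipoprotein medians were -0.92 and -0.70. With obestatin replicate 1 left out, ribosomal (0.30) and smooth muscle genes (-1.26) did not pass, and lipoprotein, fatty acid oxidation, synthesis, insulin, immediate early, mesothelial and cell cycle medians were -2.39, -1.24, -1.225, -1.06, -1.37, -2.04 and 2.69. With N-terminal peptide replicate 2 left out, immediate early (-0.375), mesothelial (-0.565) and smooth muscle genes (-0.084) did not pass, and adipocyte, synthesis, insulin, cell cycle and ribosomal medians were -1.515, -0.42, -0.29, 0.64 and 0.78. With N-terminal peptide replicate 1 left out, B cell (-1.03) and ribosomal genes (-0.049) did not pass, and lipoprotein, lipolysis, synthesis, insulin, immediate early, mesothelial and smooth muscle medians were -2.25, -1.74, -1.29, -1.03, -1.37, -2.46 and -2.20. The ribosomal median turned to -0.215 with quantile normalization, -0.11 without loess and -0.15 in the authors' log2 values, and did not pass. With the 3 samples highest in germ cell genes left out, synthesis (-0.14), fatty acid oxidation (-0.40), insulin (-0.052), lipoprotein (-0.62), immediate early (-0.315), mesothelial (-0.46) and smooth muscle genes (-0.11) did not pass, and the cell cycle median turned to -0.067 and did not pass. Adipocyte, matrix, interferon, endothelial, B cell and ribosomal medians were then -1.09, -1.32, -0.72, -1.34, -0.53 and 0.84. The B cell median was -1.998 with the scanner software's processed signals and -0.31 with no filter on dim probes, that of fatty acid oxidation -1.22 in the authors' log2 values and that of insulin genes -0.33 with the mean of all probes.

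Over all genes limma called 0 between the N-terminal peptide and obestatin, with 1869 at an unadjusted p under 0.05 (311 higher, 1558 lower). The smallest p belonged to Lyve1 (-3.49, SE 0.26), H2-Aa (-3.53, SE 0.27), C1qa (-2.90, SE 0.22), Coro1a (-2.82, SE 0.23) and H2-Ab1 (-3.06, SE 0.26), with a limma adjusted p of 0.213. Higher were Hmga2 (2.31, SE 0.38), Syt6 (2.53, SE 0.44), Erv3 (1.73, SE 0.32), Neurod2 (1.62, SE 0.31) and Rtp1 (at least 3.07-fold), with adjusted p from 0.214 to 0.228. The samples did not overlap in 38.3% of genes, against 33.3% by chance for exchangeable samples. Calls made without obestatin replicate 1 are not taken as changes, as for obestatin against saline.

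Between Nt8U and obestatin 11 of 30 lists were shifted, 7 higher with Nt8U and 4 lower. The smallest adjusted p among fat pad lists belonged to oxidative phosphorylation (0.33, adjusted p = 7.05e-07) and tricarboxylic acid cycle genes (0.56, 5.94e-05), higher with Nt8U, with an adjusted p = 0.515 for both with an estimated correlation. Fatty acid synthesis (0.79, adjusted p = 0.00836), fatty acid oxidation (0.31, 0.00585), lipolysis (0.40, 0.0381) and smooth muscle genes (0.45, 0.0266) were higher, and heat shock (-0.46, 0.0266) and macrophage genes (-0.20, 0.0255) lower. For these 6 lists the adjusted p = 0.943 with an estimated correlation. Adipocyte genes were higher by 0.39 (adjusted p = 0.0227, and adjusted p = 0.956 with an estimated correlation) and ribosomal genes lower by a median of -0.23 (0.0152, and adjusted p = 0.967 with an estimated correlation). Epididymis genes were lower by a median of -1.19 (adjusted p = 3.43e-05, and adjusted p = 0.943 with an estimated correlation). Only 5 of 19 were well above background in Nt8U replicate 1, so that size may be understated. Each of these 11 lists lost its call without at least 1 sample. Without obestatin replicate 1, adipocyte (-0.096), fatty acid oxidation (-0.076), synthesis (0.355), lipolysis (0.245), macrophage (-0.069), oxidative phosphorylation (0.295), tricarboxylic acid cycle (0.46) and smooth muscle genes (0.42) did not pass, and heat shock and epididymis medians were -0.88 and -2.06. Without Nt8U replicate 1, the ribosomal median was 0.29 and passed in the other direction, the smooth muscle median was 2.003, and epididymis (0.36), heat shock (0.13), synthesis (0.17), fatty acid oxidation (0.15), lipolysis (0.27), tricarboxylic acid cycle (0.33) and adipocyte genes (0.51) did not pass. Without Nt8U replicate 2, the smooth muscle median was -1.215 and passed in the other direction, adipocyte (0.43) and macrophage genes (-0.205) did not pass, and ribosomal, fatty acid oxidation, heat shock, lipolysis and epididymis medians were -0.79, 0.51, -0.89, 0.99 and -4.07. Without obestatin replicate 2, ribosomal (-0.023), heat shock (-0.23), epididymis (-0.96) and macrophage genes (-0.36) did not pass, and adipocyte and fatty acid oxidation medians were 0.94 and 0.64. With germ cell and epididymis scores as covariates, of the 10 lists other than epididymis genes only smooth muscle genes passed in the same direction (1.97), and ribosomal genes passed in the other (0.29). Of those that did not pass, the lipolysis (-0.03) and heat shock medians (0.21) turned, and adipocyte, synthesis, fatty acid oxidation, macrophage, oxidative phosphorylation and tricarboxylic acid cycle medians were 0.40, 0.086, 0.31, -0.18, 0.26 and 0.345. Without the 3 samples highest in germ cell genes, the smooth muscle (-0.655) and macrophage medians (0.21) turned and did not pass, and adipocyte, synthesis, fatty acid oxidation, lipolysis, heat shock, ribosomal and epididymis medians were 1.13, 1.55, 0.87, 1.011, -0.96, -0.46 and -2.32. Quantile normalization ended the calls of adipocyte (0.20), synthesis (0.33), fatty acid oxidation (0.20), lipolysis (0.29) and oxidative phosphorylation genes (0.155), and gave macrophage and tricarboxylic acid cycle medians of -0.34 and 0.28. Scaling without loess ended those of adipocyte (0.25), lipolysis (0.19), smooth muscle (0.35) and oxidative phosphorylation genes (0.16), with the ribosomal median at -0.46. The authors' log2 values ended those of adipocyte (0.235), fatty acid oxidation (0.245), lipolysis (0.185), smooth muscle (0.41) and oxidative phosphorylation genes (0.155), with the ribosomal median at -0.475. The scanner software's processed signals ended those of adipocyte (0.37), macrophage (-0.22) and smooth muscle genes (0.64), with the epididymis median at -3.54. Adipocyte (0.39) and macrophage genes (-0.195) did not pass without the dye term, nor did lipolysis genes (0.40) with no filter on dim probes. Among lists that did not pass, camera's direction was higher while the mean was below 0 for thermogenic (-0.022), lipoprotein (-0.095), feeding peptide (-0.17), mesothelial (-0.11) and germ cell genes (-0.013), and lower while the median was above 0 for skeletal muscle (0.35) and nerve genes (0.165). Adjusted over the list alone, 2 genes passed, both in the B cell list.

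Over all genes limma called 0 between Nt8U and obestatin, with 254 at an unadjusted p under 0.05 (52 higher, 202 lower). Calls made without obestatin replicate 1 are again not taken as changes. The smallest p belonged to Tas2r105 (at least 3.41-fold lower), Esm1, an endothelial proteoglycan (-2.29, SE 0.29), Phf24 (-1.56, SE 0.27), Ap1s2 (-5.98, SE 1.15) and Jchain, the joining chain of immunoglobulins (-1.73, SE 0.36), and to Syt6 (2.83, SE 0.44), Eml6 (2.64, SE 0.47), Acot6 (2.33, SE 0.43), Erv3 (1.68, SE 0.32) and Evx2 (2.27, SE 0.43), all with an adjusted p of 0.989. The 95% interval of the difference was -1.03 to 2.19 for Lep and -0.84 to 1.84 for Pparg, so differences of over 2-fold in either direction were not excluded for Lep. Adipoq, Lpl and Fasn were saturated in at least 3 of these 4 samples, and no difference is given for them. The samples did not overlap in 32.6% of genes, against 33.3% by chance for exchangeable samples.

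Nt8U differed from the N-terminal peptide in 19 of 30 lists, 16 higher and 3 lower. Macrophage (2.19, adjusted p = 5.77e-20), adipocyte (3.38, 3.77e-16), matrix (2.30, 3.21e-16), endothelial (2.18, 2.84e-15), fibroblast (2.12, 1.42e-10) and interferon genes (1.16, 7.02e-11) were higher with Nt8U, each with an adjusted p = 0.282 with an estimated correlation. Epididymis (-2.73, adjusted p = 0.00213), cell cycle (-0.89, 0.000284) and ribosomal genes (-0.58, 4.74e-07) were lower, each with an adjusted p = 0.531 with an estimated correlation, and germ cell genes lay at -0.81 (0.213). With only 5 of 19 epididymis genes well above background in Nt8U replicate 1, -2.73 may be understated. Lipolysis (1.51, adjusted p = 2.71e-06), synthesis (1.1, 5.01e-06), fatty acid oxidation (1.08, 3.31e-07), tricarboxylic acid cycle (0.60, 0.000284), insulin (0.60, 0.000446) and B cell genes (0.41, 0.0135) were higher, each with an adjusted p = 0.282 with an estimated correlation. So were lipoprotein (1.435, adjusted p = 4.74e-07), mesothelial (1.34, 0.000549), smooth muscle (1.24, 0.000284) and immediate early genes (0.63, 0.00519), with adjusted p = 0.312, 0.317, 0.522 and 0.531 with an estimated correlation. For pancreas (-0.061) and nerve genes (-0.08), which did not pass, the median was below 0 while the mean and camera's direction were higher. Adjusted over the list alone, 128 genes passed, among them 23 macrophage, 17 adipocyte, 16 matrix and 15 endothelial genes, and with fry macrophage and B cell genes were shifted (adjusted p = 0.0129 for each). Calls lost without N-terminal peptide replicate 2 were those of immediate early (0.45), smooth muscle (0.485) and cell cycle genes (-0.23), and adipocyte, insulin and ribosomal medians were then 1.83, 0.27 and -1.02. Those lost without N-terminal peptide replicate 1 were B cell (0.25) and ribosomal genes (-0.19), with cell cycle, immediate early, epididymis and smooth muscle medians at -1.65, 1.48, -1.37 and 2.39. Those lost without Nt8U replicate 1 were epididymis (0.051) and ribosomal genes (-0.13), with immediate early, mesothelial, smooth muscle and tricarboxylic acid cycle medians at 1.17, 2.02, 3.23 and 0.28. Those lost without Nt8U replicate 2 were immediate early (0.36) and smooth muscle genes (-0.34), with the ribosomal median at -1.098. With germ cell and epididymis scores as covariates, ribosomal (-0.082) and B cell genes (0.46) did not pass, and immediate early, insulin, mesothelial, smooth muscle and tricarboxylic acid cycle medians were 1.12, 0.40, 2.59, 3.32 and 0.26. In the fit without the 3 samples highest in germ cell genes, immediate early (0.265), mesothelial (0.85) and B cell genes (0.72) did not pass, and the smooth muscle median turned to -0.39 and did not pass. Adipocyte, synthesis, tricarboxylic acid cycle, fibroblast, cell cycle, ribosomal and epididymis medians were 2.17, 1.75, 1.09, 1.35, -0.53, -1.36 and -4.97 in that fit. Ribosomal genes did not pass with quantile normalization (-0.19) and lay at -0.31 without loess and -0.275 in the authors' log2 values. B cell genes did not pass with no filter on dim probes (0.11), and lay at 1.25 with the scanner software's processed signals and 0.74 in the authors' log2 values.

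Over all genes limma called 0 between Nt8U and the N-terminal peptide, with 1978 at an unadjusted p under 0.05 (1549 higher, 429 lower). The smallest p belonged to Ighm (3.98, SE 0.29), Lyve1 (3.43, SE 0.26), C1qa (2.81, SE 0.22), H2-Aa (3.32, SE 0.27) and Acp5 (4.03, SE 0.34), with an adjusted p of 0.188. Lower were Ace (-2.23, SE 0.37), Ap1s2 (-6.67, SE 1.15), Epb41l3 (-1.34, SE 0.23), Zfp868 (-1.33, SE 0.23) and Rtp1 (at least 3.25-fold), with adjusted p from 0.19 to 0.195. The samples did not overlap in 27.8% of genes, against 33.3% by chance for exchangeable samples.

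Across 15443 genes the log2 fold changes from saline had a covariance of 0.583 between Nt8U and obestatin, 0.052 between the N-terminal peptide and obestatin, and -0.004 between Nt8U and the N-terminal peptide. Unchanged groups set against the same saline samples gave a simulated covariance of 0.324 over 100 draws. The differences from it were 0.259, -0.272 and -0.328. The simulated values are the same for every pair and leave out that samples with the same replicate number were alike across groups. For instance, r was 0.984 between replicate 2 of saline and of the N-terminal peptide, against 0.648 within saline. These differences therefore do not measure similarity beyond the shared saline samples. Pearson's r was 0.678, 0.110 and -0.010 for the same pairs, beside 0.499 in the simulation, and Spearman's rho 0.737, -0.129 and -0.167, beside 0.455. The same sign was shared by 80.5%, 43.9% and 41.8% of genes, and part of any excess may come from the shared saline samples, since genes are not independent replicates. Within dyes, r was 0.685 in Cy3 and 0.792 in Cy5 for Nt8U and obestatin, 0.515 and -0.275 for the N-terminal peptide and obestatin, and 0.222 and -0.320 for Nt8U and the N-terminal peptide. With germ cell and epididymis scores as covariates, r was 0.867 for Nt8U and obestatin, 0.658 for the N-terminal peptide and obestatin and 0.622 for Nt8U and the N-terminal peptide, and without the 3 samples highest in germ cell genes it was 0.667, 0.638 and 0.220, with no simulation run for these fits. For the N-terminal peptide and obestatin r was -0.536 and 0.641 without N-terminal peptide replicates 1 and 2, 0.668 and 0.333 without saline replicates 1 and 2, and -0.039 and 0.357 without obestatin replicates 1 and 2. For Nt8U and the N-terminal peptide it was -0.159 and 0.141 without N-terminal peptide replicates 1 and 2, 0.390 and 0.533 without saline replicates 1 and 2, and 0.009 and -0.022 without Nt8U replicates 1 and 2. Over the probes well above background in all samples, r for these pairs was -0.037 and -0.173, and with the scanner software's processed signals it was 0.229 and 0.053. For Nt8U and the N-terminal peptide it was 0.009 with the mean of all probes.

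In the authors' deposited table for the N-terminal peptide, 109 probes were listed, 37 raised and 72 lowered, beside stated sizes of 552 and 212 for Nt8U and 781 and 262 for obestatin. In the authors' deposited table the largest mean log2 fold changes were 3.64 for Nrgn, 3.38 for Myom2, 3.33 for Add2, 2.94 for Abcc8 and 2.87 for Abca4. The authors' obestatin means of the same genes were 5.50, 4.27, -0.59, 4.11 and 4.63. The largest decreases in the authors' deposited table were -2.35 for Pnpla3, -2.17 for Accn2, -1.95 for Cdh7, -1.93 for AK080458 and -1.92 for Olfr1448. For Nrgn the samples of the N-terminal peptide stood at 6.32 and 0.96 in the authors' deposited table, and 39 of the 109 probes had samples over 1 apart on the log2 scale. Of the 109, 10 had a p under 0.05 in the authors' own test, per the authors' deposited table. Of the 109, 95 were kept here, and all 95 had the same direction, 69 with an unadjusted limma p under 0.05 and 0 with an adjusted one. The list was chosen on these same samples, so its direction is not independent evidence. The stated rule, applied to the deposited log2 values, left out 20686 probes (50.2%) that differed 2-fold between the saline samples. It then gave 104 raised and 144 lowered probes for the N-terminal peptide, 846 and 321 for obestatin and 839 and 304 for Nt8U. Without that removal it gave 280 and 721, 4161 and 4255, and 2940 and 1380.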

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

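The test with germ cell and epididymis scores as covariates was chosen before its result was seen, and the count of arrays per group after. For 8 lists the medians against saline lay on opposite sides of 0 in both dyes for the N-terminal peptide and for another peptide, and camera at the preset correlation found the difference itself. Between the N-terminal peptide and obestatin the difference was -0.802 for fatty acid oxidation, -1.356 for lipoprotein transport, -1.435 for interferon response, -2.365 for matrix, -2.39 for macrophage, -0.861 for B cell and -2.269 for fibroblast genes. With an estimated correlation their adjusted p lay between 0.388 and 0.463. Between Nt8U and the N-terminal peptide it was 1.077 for fatty acid oxidation, 1.435 for lipoprotein transport, 1.163 for interferon response, 2.297 for matrix, -0.893 for cell cycle, 2.19 for macrophage, 0.414 for B cell and 2.123 for fibroblast genes. With an estimated correlation their adjusted p lay between 0.282 and 0.531. In both comparisons fry found the difference for macrophage and B cell genes (adjusted p = 0.0133 and 0.0129). Against saline, the N-terminal peptide calls of fatty acid oxidation, lipoprotein, interferon, matrix, B cell and fibroblast genes were lost without its replicate 2. With the covariates those of lipoprotein, matrix, B cell and fibroblast genes were lost. Cell cycle genes did not pass against saline for the N-terminal peptide, and they were higher in the samples high in germ cell genes.

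The higher fat pad lists with obestatin and Nt8U were weighed against a smaller share of testis and epididymis RNA in those samples. With the germ cell and epididymis scores as covariates the macrophage median was 1.607 for obestatin, with a lower quartile of 1.299 over its members, against 1.649 without them, and for Nt8U 1.572, with a lower quartile of 0.774, against 1.363. The macrophage shift thus did not fall with these scores, but the fit cannot exclude such RNA as its cause. The scores enter as linear terms in log2 levels, and 7, 9 and 7 of 20 germ cell genes were saturated in 3 samples. Epididymis genes also did not move together, so that 1 mean score cannot stand for a share of epididymis RNA. The lipolysis and fatty acid synthesis lists lost their call in that fit, and such RNA stays open as a cause for all these lists. The adipocyte, matrix, endothelial, fibroblast and macrophage medians lay between 1.452 and 1.891 with obestatin and between 1.318 and 2.016 with Nt8U, ranges of 0.439 and 0.698 beside interquartile ranges over members of 0.462 to 1.172 and 0.52 to 1.502. A response of the tissue to the peptide cannot be told apart from the array, because each group was measured on 1 array, and a different share of fat in the tissue taken was not tested.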

How the results depend on the processing

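The alternatives with germ cell and epididymis scores as covariates and without the 3 samples highest in germ cell genes were chosen after seeing the data. Of the log2 fold changes of named genes under all alternatives, 1854 kept their direction and side of the threshold, 31 reversed and 19 passed it, the last only without obestatin replicate 1. Macrophage, adipocyte, matrix, endothelial and interferon genes were called in the same direction in all 19 alternatives to the values or the model for obestatin and for Nt8U, and macrophage genes for the N-terminal peptide (-0.941 to -0.456). The numbers of shifted lists were 18, 10 and 21 for obestatin, the N-terminal peptide and Nt8U against saline, 0 in each with an estimated correlation, and 2, 0 and 2 with fry. Over the other alternatives they lay between 12 and 19, 4 and 18, and 14 and 22. For the N-terminal peptide the number was 4 without the 3 samples, 5 without N-terminal peptide replicate 2 (3 higher, 2 lower) and 18 without its replicate 1 (2 higher, 16 lower). The number of genes called by limma was 0 in each comparison and alternative except 33 for Nt8U against saline without the 3 samples, and except without obestatin replicate 1. Leaving out each sample in turn, it ran from 0 to 2718 for obestatin against saline, 0 to 3548 for the N-terminal peptide against obestatin and 0 to 1397 for Nt8U against obestatin. Without that sample the dye term rests on groups whose Cy5 samples were all high in germ cell genes, and the remaining sample of a group is assumed to vary like the other groups. Without the 3 samples each lone sample is assumed to vary like the obestatin pair, the only spread left, in which 8.78% of genes were over 2-fold apart, against 51.4% in saline and 36.4% in Nt8U with all samples. Replicate number and dye coincide, and without this replicate block 0 genes were called and 18, 8 and 22 lists. Correlations of effects were 0.867 for Nt8U and obestatin and 0.622 for Nt8U and the N-terminal peptide with the covariates. Leaving out each sample in turn, they ran from 0.475 (obestatin replicate 2) to 0.844 (saline replicate 1) for Nt8U and obestatin, -0.536 (N-terminal peptide replicate 1) to 0.668 (saline replicate 1) for the N-terminal peptide and obestatin, and -0.159 (N-terminal peptide replicate 1) to 0.533 (saline replicate 2) for Nt8U and the N-terminal peptide.

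None of the genes whose direction reversed had passed the threshold, and the cause was not tested. For the N-terminal peptide against saline, Gpr39 was at -0.042 and Lipe at 0.123 with the scanner software's processed signals, Gpr39 at -0.02 in the authors' log2 values and Lipe at 0.131 with the mean of all probes. With the covariates, Ghrl was at -0.289 and Gpr39 at -0.059 for the N-terminal peptide, Lipe at -0.399 for obestatin and -0.924 for Nt8U, and between Nt8U and obestatin Pparg was at -0.097. Without the 3 samples, Ghrl was at 0.192 for obestatin and -0.012 for the N-terminal peptide, where Gpr39 was at -0.152, Adipoq at 0.212, Pparg at 0.125, Lpl at 0.1, Fasn at 0.593 and Lipe at 0.177. Leaving out each sample in turn, Ghrl ran from -3.396 to 0.279 for obestatin, -0.868 to 1.406 for the N-terminal peptide and -1.487 to 0.04 for Nt8U, and Fasn from -1.25 to 0.255 for the N-terminal peptide. Genes that were dim or saturated in a whole group were followed by the bound on their fold instead. Leaving out each sample in turn, that of Fasn ran from 0.787 to 2 for obestatin and 0.891 to 1.76 for Nt8U. Of 171 values of these bounds under the alternatives, 2 fell under 1 (both of Fasn) and 30 others moved by over 1.5 times, 21 of them upwards with the scanner software's processed signals or the authors' log2 values. Lipe ran from -0.018 to 2.068 for obestatin and -1.176 to 0.91 for the N-terminal peptide, where Gpr39 ran from -0.399 to 0.552 and Pparg from -1.35 to 0.06. Between Nt8U and obestatin Lep ran from -0.096 to 1.256 and Pparg from -0.006 to 1.009. A fit without a block for the array was not run apart, because the block could not be fitted. Median signals of 73 to 231.5 over backgrounds of 22 to 31 limit what can be said of dim probes.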

Other observations

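The tests in this part were all chosen after the result was seen. Some sperm genes were high in the obestatin samples as well. In obestatin replicates 1 and 2 Prm1 stood at 16.18 and 14.67, Tnp1 at 16.09 and 14.15 and Odf2 at 15.50 and 14.19. In replicate 1 of the other groups Prm1 lay between 12.17 and 12.74, Tnp1 between 10.95 and 12.12 and Odf2 between 10.92 and 11.28. In replicate 2 of those groups all of them were saturated. The median over the 20 genes of the difference, replicate 2 minus replicate 1, was 5.258 in saline, 5.111 in the N-terminal peptide and 4.558 in Nt8U. In each, 20 of 20 members were over 4-fold higher in replicate 2, although 7, 9 and 7 of them were saturated there. Testis RNA in these 3 samples could give such values. In obestatin this median of the differences was -1.511 with an upper quartile of -1.302, which argues against dye bias as the cause of the higher values in Cy5. Ghrl and Gpr39 were higher in the same 3 samples: Ghrl stood at 10.15 in saline, 10.70 in the N-terminal peptide and 8.81 in Nt8U replicate 2, against 6.54 to 7.04 in the other samples, and Gpr39 at 8.10, 8.41 and 7.57, against 6.57 to 6.88.

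Epididymis genes differed between samples of different groups by very different amounts. Cst11 and Cst12, cystatins of the epididymis, were saturated in saline replicate 1 (16.47 for both) and stood at 6.51 and 7.59 in N-terminal peptide replicate 1. Spint4, a secreted protease inhibitor, was not well above background in the saline samples and stood at 16.70 in N-terminal peptide replicate 1. Over the 18 genes well above background in saline replicate 1, the difference between these samples ran from -10.08 for Lcn9 to 1.70 for Rnase9, with a median of -2.50 and an interquartile range of 8.635. It was 7.29 over the 11 genes saturated in neither sample. This argues against 1 epididymis source in different shares, and RNA from different segments of the epididymis may be a candidate explanation that was not tested. Cst11, Cst12, Spint4, Prm1, Tnp1 and Odf2 were singled out here after their values were seen.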
